A study of Drosophila melanogaster with 6 samples.

How the data were processed

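The 6 libraries were poly(A)-selected RNA of whole female abdomens, 3 from flies overexpressing BuGZ and 3 from controls, all after 24 h of starvation, per the labels. Groups and replicate numbers were taken from the sample labels. The authors deposited 1 table of raw gene counts per library and 1 table for the whole series. Per the file headers the counts were made with featureCounts 2.0.1 on paired reads with the Ensembl release 110 annotation of BDGP6.46, with its default settings, which ignore strand and leave out reads that map to several places or overlap several genes. Genes with near-identical copies and genes that overlap another on either strand are therefore undercounted or uncertain. Per the submitters' processing notes FastQC, Trimmomatic, HISAT2, featureCounts and DESeq2 were used with dm6 and BDGP6; other versions and settings are not given in the sources used here. The deposited count tables list 24278 genes. Gene symbols came from a later Ensembl annotation of the same assembly by gene identifier, with 23751 identifiers matched and 527 not matched, and coordinates are those in the deposited tables. The unmatched identifiers held 0.0295% of all counts and stayed in the library totals. In the series table, 12817 of 12859 rows matched a symbol, and all of these held the same counts as the per-library tables.

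Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the 2 groups without covariates, after filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 9923 of 16703 genes with any count. Libraries were scaled by TMM, whose factors ran from 0.734 (BuGZ overexpression replicate 1) to 1.28 (control replicate 1), and levels are given as CPM of the TMM-scaled library. The common biological coefficient of variation was 0.465. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the SE of a log2 fold change was taken from the F statistic. Replicates of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 115, which does not tell separate flies from separate preparations of 1 sample. Total counts ran from 22737300 to 25246330 per library, and floors are 3 counts of a library's total, without the TMM factor that the levels carry.

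Gene lists were written from general knowledge before the data were examined, and 40 of them had at least 3 tested genes, 10 of these being cell type markers. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the 40 lists. None passed with a correlation estimated from the data, where the smallest adjusted p was 0.500. None passed fry (limma) either, a test of each list's direction planned beside camera, where the smallest adjusted p was 0.0624. Members were also adjusted over the list alone, with no correction over the 40 lists. Calls by this adjustment are therefore weaker than calls over all genes, and members that vary together are not separate findings. Genes were named by a rule set at the same time, which took BuGZ, w, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and non-overlapping groups, up to 4 called members of each list that passed or up to 3 members with the smallest p if none was called, and 10 metabolic genes whatever their values. Hsp23, Hsp26, Hsp27, Hsf, Hsp83, Clk, per and cac, and the genes named because they passed only when adjusted over a list alone, were added to the report after their values were seen. The fit was run on 10 simulated data sets with the real means and library sizes (9750 genes tested, 200 planted changes, and the proteasome list planted 2-fold lower). It found 1.2% of 2-fold, 32.1% of 4-fold and 76.3% of 8-fold changes, with 4.74% of its calls false, so changes under 4-fold were mostly out of reach. Simulated genes varied independently of each other, unlike members of the real lists, so this false share may not carry over to the real libraries. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a replicate block, the series table, stricter thresholds and leaving out each library in turn. DESeq2 on the genes that passed the edgeR filter was chosen after seeing the data.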

Results

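RNA was measured in whole abdomens of adult female Drosophila melanogaster starved for 24 h per the labels, from flies overexpressing BuGZ in the fat body (3 libraries) and from control flies (3 libraries). Overexpression relied on the Gal4 driver and UAS target system, in which a yeast transcription factor made in a chosen tissue switches on a transgene. The fat body is the fly's store of fat and glycogen and its main source of blood-borne immune peptides, and an abdomen also holds ovary, gut, muscle, cuticle-forming epidermis, oenocytes and reproductive tract. The deposited gene counts summed to between 22737300 and 24069514 per BuGZ overexpression library and to between 24219431 and 25246330 per control library. At these depths a count of 0 allows a level of up to 0.119 to 0.132 CPM (counts scaled to a common library total) from counting error alone. This floor leaves out the TMM factors, so it is approximate for the TMM-scaled levels below. The labels do not say that the replicates came from separate flies or crosses, so all p-values measure only the spread between these samples, which may be technical.

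BuGZ itself, a zinc finger protein known from spindle assembly and chromosome alignment, was higher in the libraries labelled as overexpressing it. The gene (FBgn0032600) lies on the plus strand of chromosome 2L from 16743405 to 16753704 (BDGP6.46 annotation, Ensembl release 110). Its level was 63.6, 87.7 and 66.7 CPM in BuGZ overexpression replicates 1, 2 and 3 and 44.8, 41.4 and 37.0 CPM in control replicates 1, 2 and 3, or 72.7 ± 13.1 against 41.1 ± 3.91 CPM (SD, n = 3 each). This is a 1.77-fold difference (log2 fold change 0.82 ± 0.23, SE) in RNA of the whole abdomen, and it did not pass the threshold over all genes in edgeR (adjusted p = 0.146). DESeq2 gave 0.84 ± 0.27 with an adjusted p of 0.0321, within a range of 0.0147 to 0.508 over 17 alternative settings. When counts were scaled by library totals alone the groups overlapped, with BuGZ overexpression replicate 1 at 46.7 CPM and control replicate 1 at 57.5 CPM.

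The eye colour gene w (FBgn0003996, X, 2790599 to 2796466, minus strand), which Gal4 and UAS constructs commonly carry as a marker, did not follow the groups. It stood at 749, 394 and 2555 CPM in BuGZ overexpression replicates 1, 2 and 3, at 3.79 and 2.19 CPM in control replicates 1 and 2, and at 626 CPM in control replicate 3. Its log2 fold change of 2.55 ± 1.93 (SE) did not pass in edgeR (adjusted p = 0.539). The alignment names in the file headers begin with BS for the 3 BuGZ overexpression libraries, with WF for control replicates 1 and 2 and with BF for control replicate 3, and the meaning of these letters is not given in the sources used here. The second letter parts the groups, and the first is B in the libraries with high w and W in those with low w. Whether the controls share 1 genotype, and whether both groups had the 24 h of starvation that the labels give, is therefore uncertain, and each fold change below may include such a difference.

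**Figure D1:**
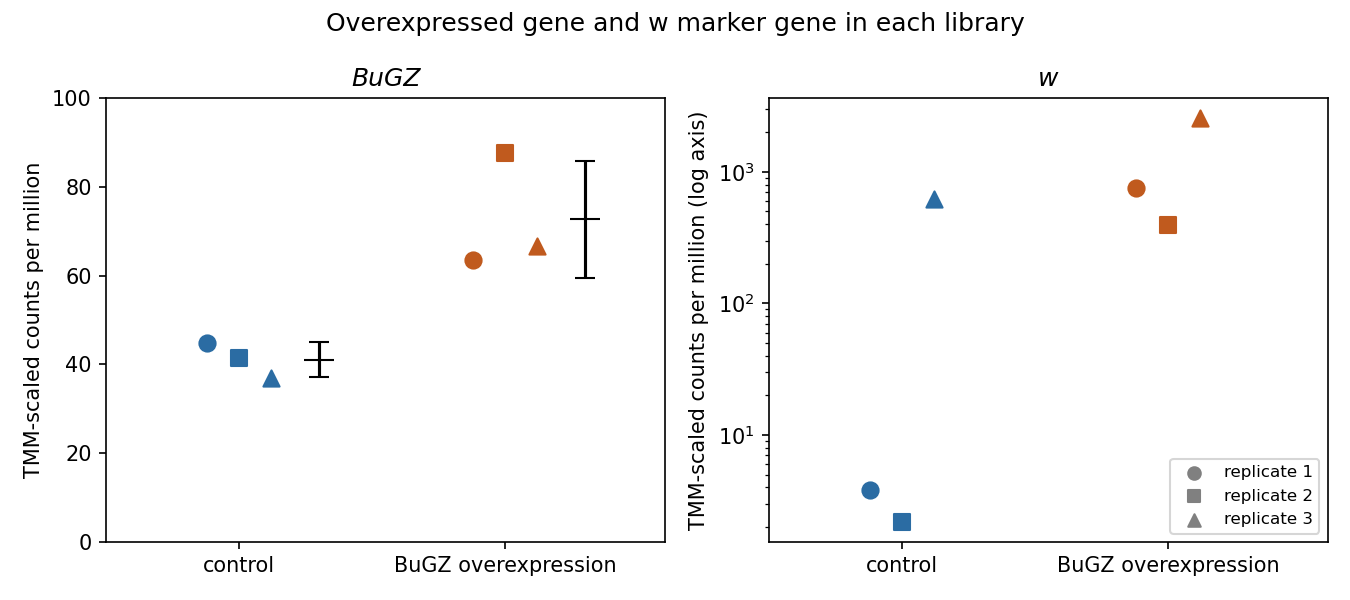
Levels of BuGZ (left, linear axis) and w (right, log axis) in TMM-scaled CPM, 1 point per library, with the mean and SD of the 3 libraries beside the BuGZ points. All 3 BuGZ overexpression libraries lie above the controls for BuGZ under this scaling, while control replicate 3 lies among the BuGZ overexpression libraries for w.

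The comparison asks which transcripts differ between the abdomens labelled as overexpressing BuGZ and the controls. Of 31 genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, 9 fell past the threshold over all genes, and the list as a whole was lost with an estimated correlation. Of 47 cuticle protein genes 3 fell past the threshold and 14 had positive values, and this list too was lost with an estimated correlation. The heat shock genes Hsp70Ab and Hsp70Bb, the antifungal peptide gene Drs, the clock gene tim and the sugar-responsive transcription factor gene Mondo rose. In all, 107 of 9923 tested genes passed an adjusted p of 0.05 in edgeR, 35 of them higher and 72 lower with BuGZ overexpression. All 107 differed by at least 2-fold, and none had overlapping groups. Over all tested genes, 25.6% had groups that did not overlap, where chance gives 10%, and 1736 genes had an unadjusted p below 0.05. Across genes, which are not independent replicates, log-scaled levels of the control libraries correlated with each other at 0.947 or higher, while BuGZ overexpression replicates 1 and 2 correlated at 0.872, below the highest value between the groups of 0.946. The number of calls was smaller whichever library was left out. It was 18, 38 and 0 without BuGZ overexpression replicate 1, 2 or 3, and 0, 23 and 5 without control replicate 1, 2 or 3. The fits by edgeR with no call still had 1287 and 1132 genes with an unadjusted p below 0.05. On all 6 libraries DESeq2 called 936 changed genes and limma-voom 113, of which 107 and 95 were among the edgeR calls.

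Several of the 10 largest rises were in genes without a described function. CG42521 rose from 0.115 ± 0.166 to 25.5 ± 7.27 CPM (SD, n = 3 each), and CG43090 from below the floor in all 3 controls to 10.1 ± 4.34 CPM. Control replicates 1 and 2 were below the floor for CG42521 too, so the size of both rises is uncertain. CG14257 had a log2 fold change of 5.95 ± 0.49 (SE) and CG43074 of 5.26 ± 0.78. The spermatheca marker CG32834 rose by 5.10 ± 0.82 on the log2 scale. The odorant-binding protein gene Obp56d rose by 5.12 ± 0.73 and hll by 4.86 ± 0.74 on the log2 scale. SPR, which encodes the receptor for the seminal sex peptide, rose from 1.01 ± 0.143 to 21.6 ± 8.22 CPM, a log2 fold change of 4.41 ± 0.40 (edgeR, adjusted p = 0.0160). The amylase gene Amy-p rose by 3.69 ± 0.55 on the log2 scale. Its level is uncertain because reads that also map to a near-identical amylase gene were left out.

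Among the 10 largest falls, CG14565 ended below the floor in all 3 BuGZ overexpression libraries and CG17298 near it, so the size of these falls is uncertain. CG17298 fell from 105 ± 48.9 to 0.202 ± 0.132 CPM, CG8534 from 287 ± 80.5 to 3.55 ± 2.20 CPM, dyw from 769 ± 350 to 11.7 ± 7.27 CPM and the peroxidase gene Pxd from 119 ± 33.4 to 1.99 ± 1.28 CPM (SD, n = 3 each). CG8630, a fatty acid desaturase family gene, had the lowest adjusted p (edgeR, 0.00939) and fell from 718 ± 100 to 14.9 ± 3.43 CPM. CG14565 and CG34217 had log2 fold changes of -8.76 ± 1.06 and -7.77 ± 1.17. In both, control replicate 2 lay lowest among the controls, at 5.73 and 14.2 CPM. Rpt6R, a paralogue of the proteasome ATPase gene Rpt6, fell by 6.45 ± 0.50 on the log2 scale, from 55.6 ± 15.4 to 0.645 ± 0.323 CPM.

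The proteasome list moved as a block. All 31 measured members had negative log2 fold changes, from -2.45 to -0.94, with a median of -1.69, a 3.23-fold lower level with BuGZ overexpression. Over all genes tested 9 members fell, and 30 fell when adjusted over the list alone. Rpn9 fell from 549 ± 111 to 100 ± 26.8 CPM, Rpt4 from 646 ± 97.8 to 147 ± 31.6 CPM, Rpn7 from 397 ± 50.3 to 106 ± 17.2 CPM and Rpn2 from 883 ± 197 to 212 ± 30.1 CPM (SD, n = 3 each). Rpn9 stood at 678 CPM in control replicate 3, the control library with high w, and at 482 and 488 CPM in the other controls. These 4 genes encode subunits of the regulatory particle that caps the proteolytic core. The groups did not overlap for 30 of the 31 members, against 25.6% of all tested genes and 10% by chance for single genes. The list passed camera (limma) with a preset correlation of 0.01 (adjusted p = 1.49e-34). It was lost with an estimated correlation of 0.854 between its genes (adjusted p = 0.500 with an estimated correlation). With the preset correlation it also passed camera in most splits that mix the groups, with an adjusted p as low as 9.78e-14. The preset test is therefore weak evidence for this grouping. In those splits the absolute list median was at most 0.90, against 1.69 between the groups.

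**Figure D2:**
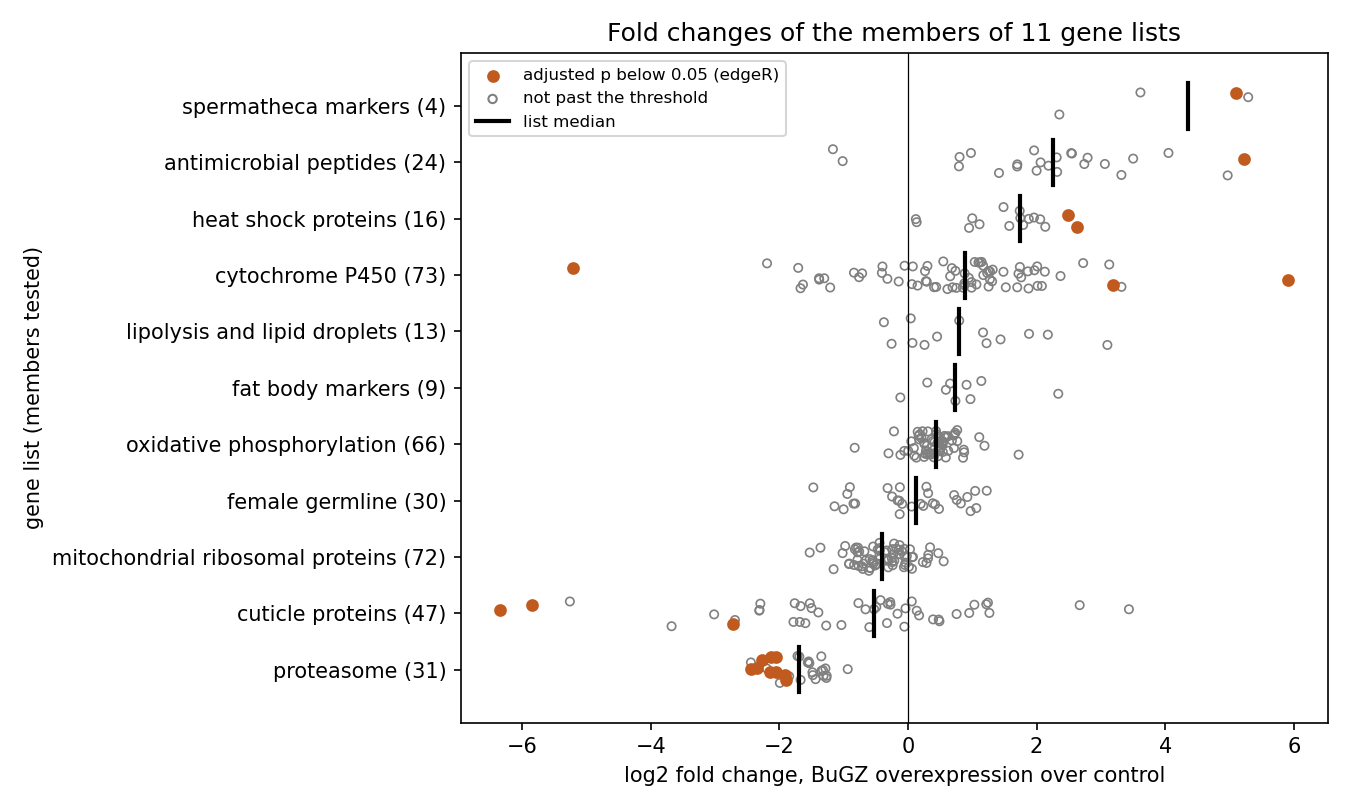
Log2 fold changes (BuGZ overexpression over control, horizontal axis) of the tested members of 11 gene lists, 1 point per gene, filled where the edgeR adjusted p is below 0.05, with the list median as a bar. All 31 proteasome genes lie below 0 and all 16 heat shock genes above 0.

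Cuticle protein genes were lower on balance and went both ways. Of 47 measured members 33 had negative values, with a median of -0.53, which ran from -1.11 to -0.25 over the alternative settings. Over all genes tested 3 fell and none rose, and adjusted over the list alone 12 fell and 1 rose, Cpr64Ac (log2 fold change 3.44 ± 0.92). TwdlT fell from 43.7 ± 16.1 to 6.59 ± 0.670 CPM, Ccp84Ab from 36.9 ± 27.8 to 0.457 ± 0.172 CPM and Cpr49Aa from 16.4 ± 13.8 to 0.288 ± 0.204 CPM (SD, n = 3 each). The list passed camera (limma, adjusted p = 0.000189) and was lost with an estimated correlation (adjusted p = 0.748 with an estimated correlation). The cytochrome P450 list held both directions as well. Cyp6w1 rose from 13.3 ± 7.79 to 121 ± 10.4 CPM and Cyp313a3 had a log2 fold change of 5.91 ± 0.77, of uncertain size since all 3 controls were below the floor, while Cyp313a1 fell by 5.22 ± 0.48 on the log2 scale. Of 73 measured P450 genes 56 were positive, with a median of 0.88 and 2 higher and 1 lower both over all genes and adjusted over the list alone (camera in limma, adjusted p = 4.09e-05, and adjusted p = 0.748 with an estimated correlation).

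Heat shock genes were higher on balance. All 16 measured members had positive log2 fold changes with a median of 1.74, of which 2 rose over all genes tested and 11 adjusted over the list alone. Hsp70Ab rose from 43.4 ± 18.1 to 242 ± 65.0 CPM and Hsp70Bb from 131 ± 70.6 to 814 ± 97.3 CPM (SD, n = 3 each). The Hsp70 copies are nearly identical and reads that map to several places were left out, so the level of each copy is uncertain. The small heat shock protein genes Hsp23, Hsp26 and Hsp27 had log2 fold changes of 2.13 ± 0.55, 1.88 ± 0.44 and 2.06 ± 0.49 (SE), and the transcription factor gene Hsf and the chaperone gene Hsp83 of 0.12 ± 0.21 and 0.13 ± 0.27, none of which passed over all genes. The list passed camera (limma, adjusted p = 9.69e-11; adjusted p = 0.500 with an estimated correlation).

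Of the 23 lists that passed camera, 8 had library medians that did not overlap between the groups, namely proteasome, heat shock, antimicrobial peptide, spermatheca, mitochondrial ribosomal, circadian, Turandot and insulin, FOXO and TOR genes. In 14 of the other 15 BuGZ overexpression replicate 2 lay below at least 1 control although the list was higher on balance, and in the remaining one, cuticle proteins, the groups overlapped too.

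Immune genes were higher on balance, but unevenly between libraries. List levels are given as the median log2 deviation from the gene means. Antimicrobial peptide genes stood at 0.73, -0.15 and 2.1 in BuGZ overexpression replicates 1, 2 and 3. They stood at -2.04, -0.35 and -0.49 in control replicates 1, 2 and 3. For Toll and Imd genes the groups overlapped, with BuGZ overexpression replicate 2 at -0.07 and control replicate 2 at 0.02. For Turandot genes these 2 libraries stood at -0.04 and -0.09. Of 24 measured antimicrobial peptide genes 22 were positive, with a median of 2.25. Drs, which encodes the antifungal peptide Drosomycin, rose from 17.9 ± 3.26 to 672 ± 604 CPM (log2 fold change 5.23 ± 0.87; edgeR, adjusted p = 0.0494), ranging from 127 to 1321 CPM within the BuGZ overexpression libraries. It was the single call over all genes, and Drs and BomS3 (2.06 ± 0.46) passed adjusted over the list alone (camera in limma, adjusted p = 1.7e-08, and adjusted p = 0.712 with an estimated correlation). Of 29 Toll and Imd pathway genes 26 were positive with a median of 0.57 and none passed over all genes or over the list alone (adjusted p = 0.00034, and adjusted p = 0.660 with an estimated correlation). The gene dl, a NF-kappaB factor of the Toll pathway, had a log2 fold change of 1.12 ± 0.28, nec of 1.81 ± 0.45 and pll of 0.94 ± 0.25. Of 13 Turandot and JAK-STAT target genes 11 were positive with a median of 0.72, none passed over all genes and 4 were higher adjusted over the list alone (adjusted p = 0.00324, and adjusted p = 0.538 with an estimated correlation). These 4, TotX, Tep2, Tep1 and TotM, had log2 fold changes of 4.73 ± 1.20, 2.52 ± 0.65, 2.42 ± 0.71 and 6.07 ± 1.84.

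In the fixed lists of fatty acid and triglyceride synthesis, lipolysis, beta-oxidation, glycolysis and trehalose, glycogen and gluconeogenesis, Mondo was the single gene called over all genes. It rose from 130 ± 14.3 to 410 ± 71.3 CPM (SD, n = 3 each; log2 fold change 1.66 ± 0.27; edgeR, adjusted p = 0.0481). It belongs to the fatty acid and triglyceride synthesis list, in which 20 of 22 members were positive with a median of 0.73 and 2 were higher (Mondo and Desat1) and 2 lower (Dgat2, -2.59 ± 0.46, and Baldspot, -1.46 ± 0.31) adjusted over the list alone (adjusted p = 0.00389, and adjusted p = 0.748 with an estimated correlation). In the same list FASN1, the fatty acid synthase gene, had 3142 ± 1330 against 1425 ± 720 CPM (adjusted p = 0.280 in edgeR) and the acetyl-CoA carboxylase gene ACC 3150 ± 1453 against 1617 ± 693 CPM (adjusted p = 0.361). In the lipolysis and lipid droplet list 11 of 13 members were positive with a median of 0.80, none was called over all genes and 6 were higher adjusted over the list alone (adjusted p = 0.000755, and adjusted p = 0.748 with an estimated correlation). The adipose triglyceride lipase gene bmm had 406 ± 85.2 against 89.9 ± 38.4 CPM (log2 fold change 2.18 ± 0.41; edgeR, adjusted p = 0.0678), CG5966 a log2 fold change of 3.10 ± 0.73, dob of 1.22 ± 0.30 and the perilipin gene Lsd-2 of 1.44 ± 0.40. The other lipase and perilipin genes fixed for naming, Hsl and Lsd-1, had 0.26 ± 0.23 and 0.45 ± 0.38, and these signs changed under library-total scaling for Hsl (-0.018) and without BuGZ overexpression replicate 1 for Lsd-1 (-0.040). Fat body markers, described with the other cell types, had a median of 0.74 in the same comparison. Their tested members all belong to other fixed lists too, among them the synthesis list, so this median is not separate evidence.

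Other metabolic lists were higher with few or no single calls. The trehalose, glycogen and gluconeogenesis list had 15 of 17 members positive, a median of 0.95, no call over all genes and 3 higher adjusted over the list alone (camera in limma, adjusted p = 0.000229, and adjusted p = 0.748 with an estimated correlation). Of these 3 tobi, a glucosidase gene, had 1371 ± 1028 against 89.5 ± 61.7 CPM, Pgm1 2931 ± 1829 against 461 ± 152 CPM and Pepck2 32.8 ± 21.5 against 7.92 ± 0.470 CPM, none past the threshold over all genes. Pepck1 had a count of 0 in each of the 6 libraries; whether its reads were lost in counting was not tested, so no level is given for it. Glycolysis genes were positive for 13 of 14 with a median of 0.72 (adjusted p = 0.00324, and adjusted p = 0.748 with an estimated correlation), with Pgi at a log2 fold change of 2.09 ± 0.51, Pfk at 1.20 ± 0.43 and Ald1 at 1.23 ± 0.45. Beta-oxidation genes were positive for 21 of 23 with a median of 0.66 (adjusted p = 0.015, and adjusted p = 0.856 with an estimated correlation), with CG3902 at 1.27 ± 0.39, Mcad at 1.23 ± 0.42 and the carnitine palmitoyltransferase gene whd at 1.08 ± 0.45. Neither list had a call, also adjusted over the list alone. In these 3 lists the groups overlapped. As the median log2 deviation from the gene means, BuGZ overexpression replicates 1 and 2 stood at 1.09 and -0.65 for beta-oxidation, where the controls ran from -0.61 to 0.12, at 1.16 and -0.55 for glycolysis (controls -0.73 to -0.01) and at 1.47 and -0.27 for trehalose, glycogen and gluconeogenesis (controls -0.77 to -0.02). The female germline list stood at -2.06, 1.14 and 0.32 in BuGZ overexpression replicates 1, 2 and 3. It stood at 0.66, -0.30 and 0.12 in control replicates 1, 2 and 3. Within each group this is the reverse of the order of the 3 lists. The synthesis, lipolysis, oxidative phosphorylation, fat body and cytochrome P450 lists had the same reversed order. Whether a different share of ovary tissue contributes to these values was not tested. Oxidative phosphorylation genes were positive for 61 of 66 with a median of 0.44 and no call by either adjustment (adjusted p = 0.00865, and adjusted p = 0.895 with an estimated correlation), and this list's median turned to -0.12 without BuGZ overexpression replicate 1. UQCR-Q, COX6B and ATPsynD in this list had log2 fold changes of 1.11 ± 0.25, 1.19 ± 0.30 and 0.87 ± 0.32. Mitochondrial ribosomal protein genes went the other way, with 60 of 72 negative, a median of -0.40 and no call by either adjustment (adjusted p = 0.000379, and adjusted p = 0.753 with an estimated correlation). Their members with the smallest p, mRpL21, mRpL14 and mRpL19, had log2 fold changes of -1.36 ± 0.33, -0.98 ± 0.28 and -0.78 ± 0.24.

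The clock gene tim rose from 91.5 ± 28.8 to 426 ± 134 CPM (SD, n = 3 each; log2 fold change 2.22 ± 0.37; edgeR, adjusted p = 0.0494). In its circadian list 7 of 8 members were positive with a median of 0.74, and 3 (tim, Pdp1 and cwo) were higher adjusted over the list alone (camera in limma, adjusted p = 0.000825, and adjusted p = 0.500 with an estimated correlation). Clk had a log2 fold change of -0.10 ± 0.23 and per of 0.60 ± 0.25. The labels used here give no time of day for the dissections. In the insulin, FOXO and TOR list 16 of 22 genes were positive with a median of 0.41, none was called over all genes, and 3 (Lk6, Ilp6 and tobi) were higher and REPTOR (-1.21 ± 0.34) lower adjusted over the list alone (adjusted p = 0.0317, and adjusted p = 0.748 with an estimated correlation). The insulin-like peptide gene Ilp6 had 25.1 ± 13.6 against 4.98 ± 0.930 CPM (edgeR, adjusted p = 0.0710) and the kinase gene Lk6 1466 ± 433 against 440 ± 61.6 CPM (adjusted p = 0.0645), while the insulin receptor gene InR and the translational repressor gene Thor had log2 fold changes of 0.69 ± 0.38 and 0.34 ± 0.32. The lipoprotein and storage protein list had 9 of 11 positive, a median of 0.59 and 1 higher adjusted over the list alone, LpR2 (log2 fold change 2.42 ± 0.42; edgeR, adjusted p = 0.0537), with LpR1 at 1.45 ± 0.61 and Fbp2 at 1.28 ± 0.66 (list adjusted p = 0.0229, and adjusted p = 0.748 with an estimated correlation). The UDP-glycosyltransferase list (19 of 27 positive, median 0.65) and the amino acid and one-carbon catabolism list (16 of 22 positive, median 0.36) had no call by either adjustment (adjusted p = 0.027 and 0.0318, and adjusted p = 0.795 and 0.748 with an estimated correlation). Ugt36E1 and Ugt35A1 had log2 fold changes of 1.26 ± 0.28 and 2.21 ± 0.53, and Got1 and Sardh of 2.13 ± 0.46 and 2.79 ± 0.69.

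**Figure D3:**
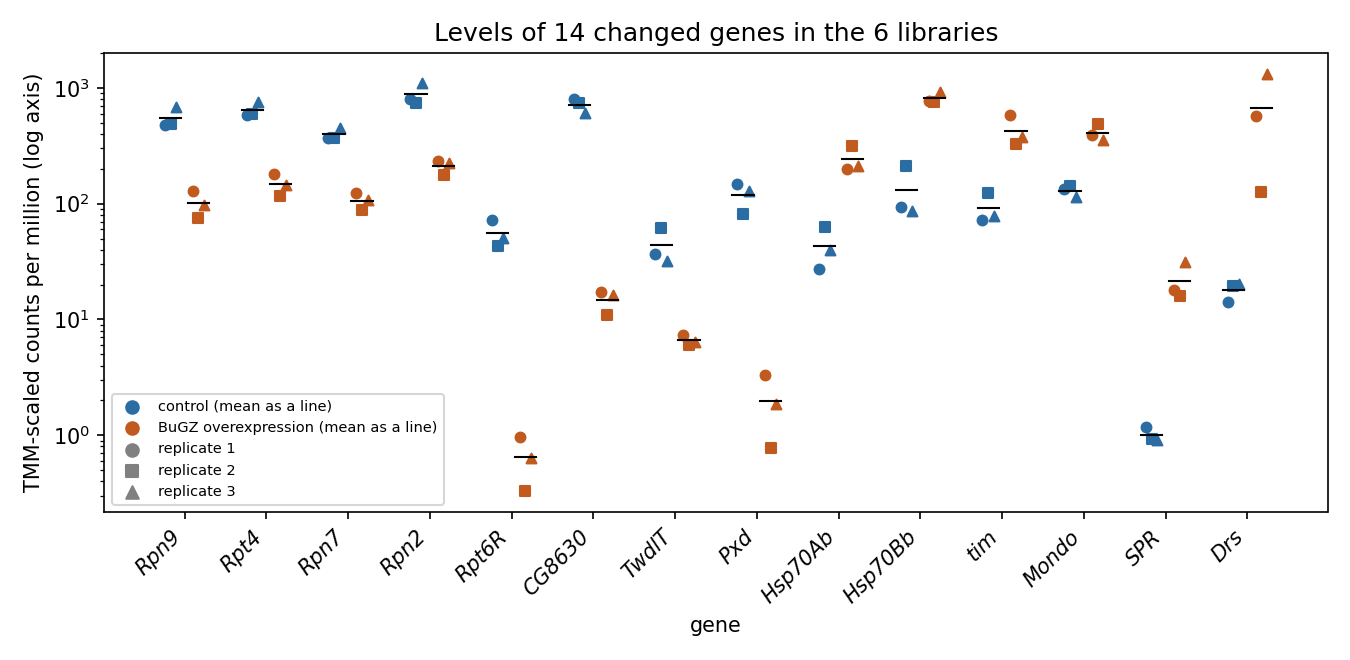
Levels of 14 genes past the edgeR threshold in TMM-scaled CPM (log axis), 1 point per library with the replicate as its shape and the group mean as a line. The 3 BuGZ overexpression libraries lie below all 3 controls for Rpn9 through Pxd and above them for Hsp70Ab through Drs.

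Markers of cell types were tested in the same way, and 4 of 10 such lists passed. All 4 measured spermatheca markers, secreted proteins of the female sperm store, were positive with a median of 4.36, which ran from 3.18 to 5.29 over the alternative settings. BuGZ overexpression replicates 1 and 3 carried most of this, at 2.57 and 1.82 (median log2 deviation from the gene means), while replicate 2 stood at -0.63 beside control replicate 1 at -0.80, and the groups did not overlap for 2 of the 4 markers. CG32834 rose from 2.50 ± 2.50 to 86.7 ± 37.3 CPM (SD, n = 3 each) and was the single call over all genes, while all 4 were higher adjusted over the list alone (camera in limma, adjusted p = 1.96e-05, and adjusted p = 0.500 with an estimated correlation). Fat body markers were positive for 8 of 9 with a median of 0.74, no call over all genes and 1, Desat1, higher adjusted over the list alone (adjusted p = 0.00842, and adjusted p = 0.748 with an estimated correlation). All 9 also belong to the synthesis, the insulin, FOXO and TOR, or the lipoprotein and storage protein list, and are not independent of those. The desaturase gene Desat1 had 5843 ± 2338 against 1156 ± 639 CPM, and Lpin 488 ± 109 against 249 ± 55.0 CPM. Midgut and digestive enzyme markers were positive for 8 of 11 with a median of 0.63, with Amy-p called and 3 (Amy-p, Amy-d and LysB) higher adjusted over the list alone (adjusted p = 0.0196, and adjusted p = 0.500 with an estimated correlation). Hemocyte markers were positive for 8 of 12 with a median of 0.57, no call over all genes and 1, srp, higher adjusted over the list alone (adjusted p = 0.0343, and adjusted p = 0.783 with an estimated correlation), with srp at a log2 fold change of 1.67 ± 0.36, Sr-CI at 1.36 ± 0.43 and PPO2 at 2.43 ± 0.77.

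The remaining lists did not pass. Female germline genes had 16 of 30 positive with a median of 0.13 (adjusted p = 0.486), and eggshell genes 11 of 12 positive with a median of 2.09 (adjusted p = 0.0897), with no call in either. These medians average libraries that differed widely, since the germline list stood at -2.06 and 1.14 and the eggshell list at -2.03 and 2.69 in BuGZ overexpression replicates 1 and 2 (median log2 deviation from the gene means). Neuronal markers had 1 call among 13, the calcium channel gene cac (log2 fold change 3.16 ± 0.45), over all genes and adjusted over the list alone (median 0.45, adjusted p = 0.194). Muscle markers (22 genes, median 0.39, adjusted p = 0.486), oenocyte markers (8, 0.53, 0.442) and Malpighian tubule markers (15, -0.25, 0.236) had none over all genes. No call was made over all genes among the yolk protein genes (3 genes, median 0.34, adjusted p = 0.788), autophagy genes (24, -0.05, 0.973), unfolded protein response and endoplasmic reticulum chaperone genes (22, 0.05, 0.917), cytosolic ribosomal protein genes (84, 0.16, 0.330) or mitotic spindle and checkpoint genes (31, -0.29, 0.0550). The same held for ecdysone response (15, 0.54, 0.628), juvenile hormone response (8, 0.54, 0.522), glutathione transferase (31, 0.24, 0.380), oxidative stress defence (18, -0.16, 0.788), cell death (12, -0.17, 0.758) and V-ATPase genes (22, 0.02, 0.788). Adjusted over the list alone, Zasp52 was higher and tn lower among muscle markers, bond was lower among oenocyte markers, gce was higher and Jhe lower among juvenile hormone response genes, and Cyp18a1, Eip75B and Blimp-1 were higher and Hr4 and Eip74EF lower among ecdysone response genes, while the others of these lists had none. The median, the mean and the direction of the camera test differed in sign for the female germline, muscle, autophagy, unfolded protein response and V-ATPase lists. Of 24 testis and accessory gland markers 1 was measurable, so that list was not tested.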

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

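The count of changed genes moved with the tool, the scaling and the filter, and for none of these was the cause tested beyond what the setting itself changes. DESeq2 called 936 genes (480 higher, 456 lower, or 51.3% higher against 32.7% in edgeR) and, on the genes of the edgeR filter, a setting chosen after seeing the data, 1005 (529 higher, 476 lower, 52.6%); BuGZ passed in both, at log2 fold changes of 0.84 and 0.85. Scaling by library totals alone shifted the median of all genes by -0.31 on the log2 scale and gave 258 calls (61 higher, 197 lower), so these are relative to that shift. Without a low-count filter 171 genes passed (69 higher), a minimum mean of 5 CPM left 20 higher calls, and the series table, which holds fewer genes, also left 20. An adjusted p of 0.01 left 1 gene (0 higher, 1 lower) and 2 marker lists. With an estimated correlation 0 gene lists and 0 marker lists passed camera. No list passed fry, where adjusted p-values were 0.0624 or higher. The label numbers are not taken as pairs, since deviations from the group means correlated at -0.49, -0.46 and 0.29 between samples of the same number. The alignment names number control replicates 1, 2 and 3 as 2, 3 and 3. By these BuGZ overexpression replicate 2 correlated at 0.51 with control replicate 1, and replicate 3 at -0.18 and 0.29 with control replicates 2 and 3. The highest value, 0.56, was between BuGZ overexpression replicate 1 and control replicate 2, whose alignment numbers, 1 and 3, do not match. These values do not favour a pairing by the alignment numbers, which stays open. With the replicate block edgeR called 0 genes (0 higher, 0 lower), with 954 at an unadjusted p below 0.05. Leaving out 1 library at a time gave 0 to 38 changed genes, 0 to 20 higher and 0 to 20 lower, 14 to 26 gene lists and 2 to 5 marker lists, and log2 fold changes of 0.67 to 0.92 for BuGZ. The signs of Hsl (-0.018 with library totals), Lsd-1 (-0.040 to 0.65 over the fits without 1 library, the lowest without BuGZ overexpression replicate 1) and the oxidative phosphorylation median (-0.12 to 0.75 over those fits, the lowest without the same library) reversed, and the cause was not tested. For the 32 named genes past the threshold, all 537 values under the alternatives kept their direction and 333 kept their call. The kept direction adds little support, since these genes were chosen for being called and none of the calls had overlapping groups. Without control replicate 3, 5 of the 32 kept their call, and with the replicate block 0 did. No gene at all was called without BuGZ overexpression replicate 3 or without control replicate 1. The 23 lists that passed kept direction and call in 309 of 345 values, those with an estimated correlation left out. At total counts of 22737300 to 25246330 a count of 0 allows up to 0.119 to 0.132 CPM by library totals, so TMM-scaled levels near or under this are not resolved.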

Other observations

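Genes outside the fixed lists moved beside the proteasome genes, and were picked out after their values were seen. The proteasome-bound deubiquitinase genes Usp14 and Uch-L5 fell by 2.44 ± 0.35 and 2.67 ± 0.29 on the log2 scale (SE), and the ubiquitin hydrolase gene Uch by 2.01 ± 0.28. The ubiquitin chain elongation factor gene Ube4B had a log2 fold change of -2.81 ± 0.45, the peptidase gene TppII of -2.27 ± 0.32 and the proteasome subunit gene Sem1 of -1.65 ± 0.24. Each of these 6 genes passed the edgeR threshold. The proteasome maturation gene Pomp, with a log2 fold change of -1.43 ± 0.34, did not pass (edgeR, adjusted p = 0.111). The ubiquitin genes Ubi-p63E and Ubi-p5E had log2 fold changes of 0.46 ± 0.45 and -0.60 ± 0.33 and did not pass. The actin filament capping gene tmod also fell (1231 ± 452 against 228 ± 72.3 CPM, control first), while the fixed muscle marker list had 16 of 22 members positive and did not pass. The heme oxygenase gene Ho fell by 3.14 ± 0.49 on the log2 scale. The heat-inducible noncoding RNA lncRNA:Hsromega rose by 1.54 ± 0.26 on the log2 scale and the lectin gene lectin-28C by 3.52 ± 0.47.

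Each of the tests of an explanation below was chosen after the result was seen, while the counts over other splits of the libraries were planned. The 6 libraries make only 10 splits into 3 and 3, too few for a share below 0.05. The real split gave 107 changed genes (1 of 10 splits with as many, 0 in the highest other), 23 gene lists (4 of 10, 26 in the highest other) and 4 marker lists (7 of 10, 8 in the highest other).

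Among the 40 tested lists, the proteasome list had the highest share of members whose groups did not overlap, 30 of 31. The choice among the scalings tried does not give the fall of these genes, since the list median stayed at -1.68 or lower under 4 other scalings. Those scalings moved the median of all genes by -0.31 to 0.02 on the log2 scale. A scaling error common to all was not tested, since shifts this small could not undo the fall of the proteasome genes. A smaller share of ovary tissue would lower germline genes with them, and the female germline list had a median of 0.13 (quartiles -0.30 and 0.66) against -1.69 (quartiles -2.05 and -1.39); in BuGZ overexpression replicate 2 the germline level was the highest of the 6 libraries (1.14, median log2 deviation from the gene means) and the proteasome level the lowest (-1.51), while replicate 1 had the lowest germline level (-2.06) and, of the BuGZ overexpression libraries, the proteasome level nearest the controls (-0.43). A difference in feeding between the groups would set genes repressed by starvation apart from genes induced by it; both lay above 0, with medians of 0.85 (8 genes) and 0.79 (10 genes) and no single call, so these lists, written from general knowledge after the data were seen, leave it open, and the second letter of the alignment names parts the groups too. BuGZ overexpression is the difference that the design names and may act on these genes, but it was not tested apart from anything else that differs between the groups.

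A list of cuticle genes active in late pupae and newly eclosed adults, written after Cht5, obst-A and TwdlT had been seen among the calls, had a median of -1.44 over 18 genes. The choice among the scalings tried does not account for this, since the median was -1.44 or lower under 4 other scalings. Those scalings differed too little to test a larger scaling error. Whether the control flies were at an earlier stage of adult maturation stays open, because the list was chosen for this theme, so the median of -1.31 over its 15 members that were not called decides nothing. Ddc (log2 fold change 0.16 ± 0.58) and mwh (0.14 ± 0.44) were the positive members, and the abundant Acp65Aa (-0.29 ± 0.63) differed by less than its error. An effect of the overexpression on maturation or on epidermis could give the same values, and no age is given in the labels used here.

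The level of w in control replicate 3 was 209 times the mean of control replicates 1 and 2. A transgene carrying the w marker in this library is a candidate explanation that stays open. Of 22 tested genes within 100 kb of w, 20 differed by under 2-fold between the same libraries (median log2 ratio -0.09, against 7.71 for w). CG2680 and CG2681 were lower in control replicate 3, at -5.79 and -2.57. The neighbours cannot tell a transgene from a difference in the w gene at its own place, which could leave them unchanged too. A mislabelled BuGZ overexpression library is argued against, though weakly, by the BuGZ level of 37.0 CPM in control replicate 3. It was the lowest of the 6 libraries by TMM and by library totals. BuGZ marks the groups poorly, since by library totals BuGZ overexpression replicate 1 (46.7 CPM) lay below control replicate 1 (57.5 CPM). Log-scaled levels of control replicate 3 correlated at 0.964 and 0.966 with the other controls and at most 0.946 with a BuGZ overexpression library. The second letter of the alignment names joins the controls too, so these correlations do not tell the group from whatever that letter marks. On the other side, the alignment name of control replicate 3 begins with B, as in the BuGZ overexpression libraries, and its w level lay among theirs. Without control replicate 3 the count of changed genes was 5, while no gene was called without control replicate 1. No biological explanation was tested for this pattern.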
